A study of Arabidopsis thaliana with 22 samples.

How the data were processed

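Bulk mRNA sequencing of Arabidopsis thaliana upper primary roots was compared between Col-0 (WT) and myb67 mutant seedlings sown together, in 2 experiments with 6 and 5 libraries per genotype. Each library is a biological replicate per the labels. The authors deposited a table of 33323 genes by 22 libraries and their own comparison of the genotypes. In experiment 1 the deposited values are expected counts per gene in steps of 0.5, with 28.2% to 34.6% of the values per library not whole, and in experiment 2 the deposited values are raw counts, all whole numbers. Neither is normalized. The authors' processing notes name FastQC, Trimmomatic 0.39, STAR 2.7.10a, HOMER, DESeq2 1.40.1 and the genome build TAIR10, with no role or order. How strand, read pairs and multi-mapping reads were counted is not given in the sources used here, nor is the reason for the steps of 0.5. The authors' deposited comparison gives a log2 fold change with its standard error, an adjusted p value (p_value, method of adjustment not given) and a mean signal of scaled counts per gene.

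Values of experiment 1 were rounded to whole numbers before fitting. Genes were kept by filterByExpr of edgeR on the 4 groups of genotype and experiment, which left 21683 genes, and libraries were scaled by TMM, with factors that ran from 0.709 in WT replicate 1 of experiment 1 to 1.05. The genotype effect over both experiments was tested with the quasi-likelihood F test of edgeR with the experiment as a term. A fit of the 4 group means gave the effect in each experiment and the difference between them. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Levels are given as TMM-scaled CPM, computed by edgeR. Counts per library ran from 3705515 to 17727642 in experiment 1 and from 23190477 to 32091009 in experiment 2. No pair of replicates was a duplicate, as the chi-square per gene between replicates was at least 2.193. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

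The design, the tests, the rule for named genes and 28 gene lists were fixed before the data were examined. Named genes were MYB67, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 CPM and the same sign in both experiments, up to 4 called members of each list, any suberin gene, and the 5 genes of smallest p for the difference between experiments. The lists held 402 members, of which 375 were tested. Of the others, 4 were left out because the reference gives their identifier another name (SGN3, PEAR1, GXM3 and PRX73), and the rest were too low. For 18 members the reference holds no symbol. Lists were tested with camera of limma on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 28 lists, beside camera with an estimated correlation and fry. Permutation of each list's mean log2 CPM within experiments was added after the data were seen (100000 permutations, smallest p 1e-05). The reference annotation, a later release than the authors' build, was used for names, products and the order and overlap of genes, and no position is given for that reason. Of the 33323 genes, 488 have no locus tag in it.

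Whether replicate numbers pair the libraries was tested by the correlation, across genes, of the deviations from group means between WT and myb67 libraries of the same number. Genes are not independent replicates. It was 0.285 to 0.671 in experiment 2, lowest for replicate 5, which matched replicate 4 of the other genotype best in both directions, and -0.158 to 0.0430 in experiment 1, where above 0.1 was taken as paired. Fits with the replicate number as a block are given beside the others. The alternatives were another normalization (RLE, upper quartile), no filter and a stricter filter, a robust prior, limma-voom, DESeq2, no experiment term, each experiment on its own, a fold threshold, the replicate block, other list tests and leaving out each library in turn. Alternatives added after the data were seen were a block in experiment 2 only, unrounded values, leaving out the 3 libraries of fewest counts (WT replicate 1 and myb67 replicates 3 and 4 of experiment 1), leaving out WT replicates 3 and 6 of experiment 1, and leaving out genes that overlap another tested gene. On simulated changes in 100 genes per fold, the fit over both experiments called 84% of genes changed 1.5-fold and 95% of genes changed 2-fold, with 6 false calls. These shares were 66% and 90% in experiment 1, 70% and 90% in experiment 2, and 48% and 69% for the difference. A simulated list of 15 genes raised 1.3-fold passed with a preset and with an estimated correlation, and 0 of the other 27 lists did. The simulated genes were drawn independently, while the estimated correlation within the real lists reached 0.876 (photosynthesis). The simulation therefore does not test false calls of correlated lists. Its libraries were also drawn without replicate pairs and without libraries that stand apart. The shares called and the false calls per gene therefore do not cover such structure in the real libraries.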

Results

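Bulk mRNA sequencing was carried out on the upper primary root of 14-day-old Arabidopsis thaliana seedlings, taken over 1.5 cm below the hypocotyl with lateral roots removed and pooled from about 40 seedlings per sample. Wild type (WT, accession Col-0) was compared with a line labelled myb67, a mutant of the R2R3-type transcription factor gene MYB67 in the same accession. There were 2 experiments. Experiment 1 held 6 libraries of each genotype and experiment 2 held 5 of each, 22 libraries in all. Total counts per library ran from 3705515 to 17727642 in experiment 1 and from 23190477 to 32091009 in experiment 2, and 21908 to 24293 and 29026 to 31259 genes had a count above 0. WT replicate 1 of experiment 1 had the fewest counts, and the ribosomal RNA gene AT3G41768 took 27.7% of them (95% exact binomial interval 27.7% to 27.8%, which covers counting error only). The same gene took at most 0.505% in the other libraries of experiment 1 and 0.645% to 1.75% in experiment 2. Fold changes are myb67 over WT, with an approximate standard error (SE), and levels are library-scaled counts (CPM) with the SD between libraries. Each SE was derived from the edgeR test, as the size of the log2 fold change over the square root of its F statistic. It is not the standard error of a fitted coefficient.

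MYB67 itself (AT3G12720) was measured first, because its level bears on the genotype labels. Its level was higher, not lower, in the libraries labelled myb67. In experiment 1 it was 6.58 ± 0.437 CPM (SD, n = 6) in WT and 11.6 ± 1.66 CPM (SD, n = 6) in libraries labelled myb67, and in experiment 2 it was 10.6 ± 2.79 CPM (SD, n = 5) and 18.0 ± 3.68 CPM (SD, n = 5). Over both experiments the log2 fold change was 0.79 (SE 0.11; edgeR quasi-likelihood adjusted p = 6.89e-05). All 11 libraries labelled myb67 lay above every WT library of their own experiment. Within experiments the log2 fold change was 0.83 and 0.77, and the difference between them did not pass the test (edgeR adjusted p = 0.978). The call was lost when the experiment was not fitted (edgeR adjusted p = 0.0550). The labels do not say where in the gene the allele lies or what it does to the transcript, so a count over the whole gene does not test the genotype, and every direction below is that of libraries labelled myb67.

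**Figure D1:**
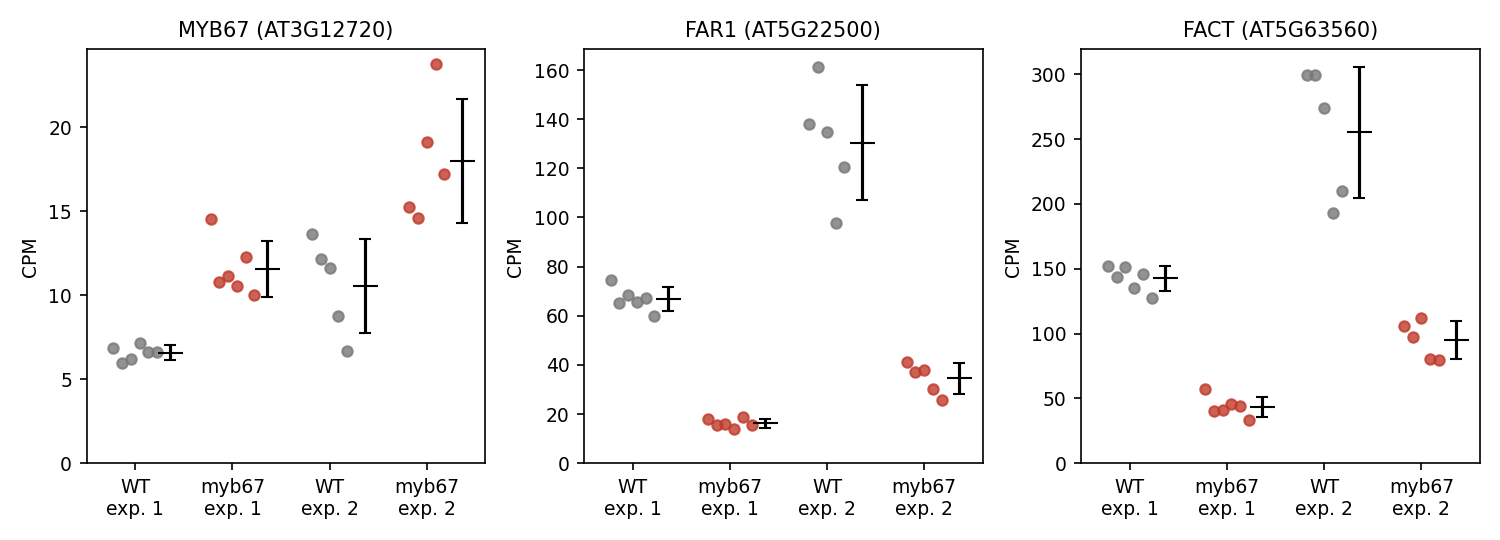
CPM of MYB67, of the fatty acyl reductase FAR1 and of the acyltransferase FACT in each library (dots), by genotype and experiment, with mean and SD (bars). MYB67 was 6.58 CPM in WT and 11.6 CPM in libraries labelled myb67 in experiment 1, and FAR1 and FACT were lower in all 11 libraries labelled myb67.

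Over both experiments, 326 of 21683 genes passed an adjusted p of 0.05 between the genotypes (edgeR, with the experiment as a term), 177 higher and 149 lower in libraries labelled myb67. The falls were the larger changes. MRD1 (AT1G53480), a gene of unknown function, had 0 to 1 counts in the 6 libraries labelled myb67 of experiment 1, where WT libraries had 107 to 795.5, and its level in experiment 2 was 0.746 ± 0.949 CPM (SD, n = 5) against 52.15 ± 2.59 CPM (SD, n = 5) in WT. Replicate 2 of the libraries labelled myb67 carried most of that level, with 2.359 CPM against 0.1131 to 0.8461 CPM in the other 4, and without it the log2 fold change over both experiments was -7.82 in place of -6.71. Its neighbour HEI10 (AT1G53490), a ubiquitin ligase known from meiotic recombination, fell by 3.42 on the log2 scale (SE 0.07), and the annotated spans of both genes overlap, and HEI10 lost 40.31 CPM in experiment 1, where MRD1 had 43.35 CPM in WT. The transcription factor gene MYB69 (AT4G33450) had a log2 fold change of -5.47 (SE 0.23), from 9 to 87.5 counts per WT library to 0 to 1 in libraries labelled myb67 in experiment 1. The cytochrome P450 gene CYP702A6 (AT4G15396) had a log2 fold change of -4.71 (SE 0.19), from 14.3 ± 0.785 to 0.405 ± 0.237 CPM (SD, n = 6) in experiment 1. Next came AT1G23200 of the invertase and pectin methylesterase inhibitor family (-3.40), AT5G43690 of the P-loop nucleoside triphosphate hydrolase family (-3.34) and the lipid-transfer protein gene AT3G58550 (-3.29), whose span overlaps AT3G58540. The ABC transporter gene ABCA8 (AT3G47790, -2.44), the terpenoid cyclase gene BAS (AT1G78950, -2.27), the heat shock factor gene HSFB3 (AT2G41690, -2.01), FAR1 (AT5G22500, -1.97) and the uncharacterised gene AT3G09950 (-1.94) completed the 12 largest falls. All 12 were lower in the 11 libraries labelled myb67 than in any WT library of their experiment.

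The largest rises began from low levels. The acyl-CoA reductase gene AT3G11980 (MS2), known from pollen wall formation, rose from 0.144 ± 0.121 to 3.21 ± 0.680 CPM (SD, n = 6) in experiment 1 and from 0.198 ± 0.125 to 1.46 ± 0.143 CPM (SD, n = 5) in experiment 2, with a log2 fold change of 3.44 (SE 0.27; edgeR adjusted p = 4.98e-09). The ABC transporter gene ABCG31 (AT2G29940) had a log2 fold change of 3.06 (SE 0.24), reaching 7.39 CPM in experiment 2. The kelch-repeat gene AT5G40680 followed with 2.96, the RNA-binding protein gene PUM12 (AT5G56510) with 2.62, AT5G44925 with 2.41, AT5G52390 with 2.05 and the receptor-like protein gene RLP6 (AT1G45616) with 2.04. The list ended with the actin family gene AT2G42170 (1.77), the protein phosphatase 2C gene AT4G32950 (1.73), AT2G01810 (1.65), AT2G16586 (1.58) and the alternative oxidase gene AOX1D (AT1G32350). AT3G11980 lies among the 100 tested genes on either side of MYB67, where 5 genes besides MYB67 were called and the 95th percentile of such windows was 6. Of the 326 genes, 325 had the same sign in both experiments, 80 changed at least 2-fold (37 up, 43 down) and 172 changed by less than 1.5-fold. The equal signs are no independent check, since the fit over both experiments favours genes whose effects agree. The annotated span of 63 of the 326 overlaps another tested gene, a lower share than the 5923 of all 21683 genes tested. Without the term for the experiment, 83 genes passed.

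**Figure D2:**
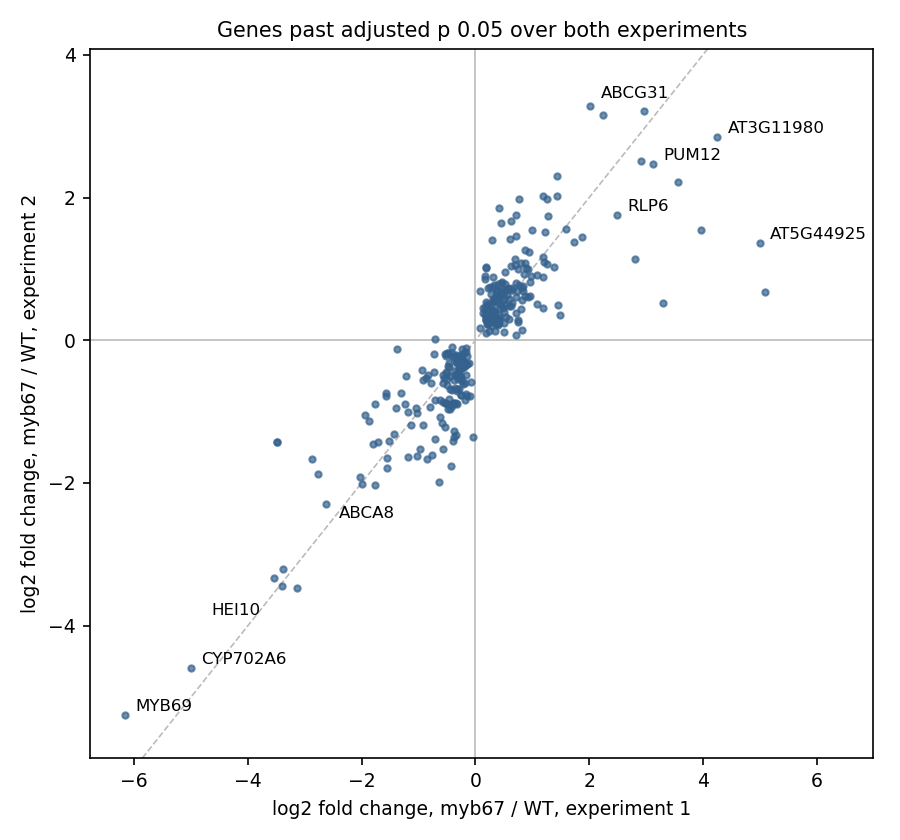
Log2 fold change of each called gene in experiment 1 (x axis) and in experiment 2 (y axis), with the line of equal change dashed. MRD1 is left out because its level in experiment 1 rests on 1.5 counts over 6 libraries. The same sign on both axes is found for 325 of all 326 called genes, which the fit over both experiments favours.

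The suberin genes split. Suberin is the lipid polyester of endodermis and phellem (cork) walls, and the series, which set out to find what MYB67 regulates, links it by its title to phellem. Of 22 tested genes of suberin synthesis and export, 4 rose, 3 fell and 15 did not pass the test (11 rose and 3 fell when adjusted over the list alone). The 2 largest falls were those of FAR1 and FACT. FAR1, which reduces fatty acyl groups to primary alcohols, fell from 66.8 ± 4.81 to 16.2 ± 1.76 CPM (SD, n = 6) in experiment 1 and from 130.5 ± 23.4 to 34.5 ± 6.27 CPM (SD, n = 5) in experiment 2 (edgeR adjusted p = 2.34e-14). FACT (AT5G63560), which joins caffeate to fatty alcohols, fell from 143 ± 9.61 to 43.4 ± 7.97 CPM (SD, n = 6) and from 255 ± 50.5 to 95.04 ± 14.7 CPM (SD, n = 5), a log2 fold change of -1.57 (SE 0.09; edgeR adjusted p = 3.21e-11). FAR4 (AT3G44540), another reductase, fell by 0.33 (SE 0.08), and the third reductase, FAR5 (AT3G44550), had 0.12 (SE 0.09; edgeR adjusted p = 0.959). The rises were smaller: the elongase gene KCS2 (AT1G04220) with 0.78 (SE 0.13), the transporter gene ABCG2 (AT2G37360) with 0.58 (SE 0.06), the hydroxylase gene CYP86A1 (AT5G58860) with 0.36 (SE 0.07) and the acyltransferase gene GPAT5 (AT3G11430) with 0.35 (SE 0.07). ABCG2 overlaps AT2G37362, and KCS2 overlaps AT1G04210. The feruloyl transferase gene ASFT (AT5G41040) had 0.23 (SE 0.08; edgeR adjusted p = 0.281), and CYP86B1 (AT5G23190) had 0.12 (SE 0.07; edgeR adjusted p = 0.870). With the replicate pairs of experiment 2 in the model, AT1G74460 also passed as higher over both experiments (0.26; edgeR adjusted p = 0.0414, against 0.142 without the pairs and 0.102 with a block in both experiments). In experiment 2, ASFT (edgeR adjusted p = 0.0352), AT5G37690 (0.00585), AT2G23540 (0.0292) and AT1G74460 (0.0203) were higher and FAR4 (0.00281) was lower only with the pairs in the model. Without the 3 libraries of fewest counts, the call of FAR4 was lost (edgeR adjusted p = 0.0538).

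As a set, suberin synthesis moved up against the other genes (limma camera adjusted p = 1.37e-04 with the preset correlation), a call that was lost with an estimated correlation (adjusted p = 0.589) and by permutation of the list's mean (adjusted p = 0.948). The median of the members was 0.15 and their mean 0.01. By experiment, camera gave an adjusted p of 0.542 in experiment 1, of 1.08e-06 in experiment 2 and of 0.00123 for the difference, and with an estimated correlation of 0.920, 0.319 and 0.557. Lists of other tissues also passed in experiment 2 by camera (adjusted p of 0.00409 to 0.0319). Cambium, phloem and xylem were higher there, and endodermis and root hairs were lower. A test for change in either direction passed (fry mixed adjusted p = 6.89e-21). The regulators of suberin rose as a set by camera (adjusted p = 3.10e-04) and by fry (adjusted p = 0.0336). They did not pass by camera with an estimated correlation (adjusted p = 0.146) or by permutation of the list's mean (adjusted p = 0.195). Of 16 members, 3 were higher, none lower and 13 did not pass (4 higher when adjusted over the list alone). The mean differences were 0.11 in experiment 1 (camera adjusted p = 0.0799) and 0.14 in experiment 2 (camera adjusted p = 0.00127, and 0.234 with an estimated correlation). NAC058 (AT3G18400) had 0.38 (SE 0.06), MYB9 (AT5G16770) 0.33 (SE 0.08) and MYB93 (AT1G34670) 0.31 (SE 0.08). MYB9 lost its call in 7 of the 22 fits that left out 1 library (myb67 replicates 2 and 5 of experiment 1, WT replicates 4 and 5 and myb67 replicates 2, 4 and 5 of experiment 2), with log2 fold changes of 0.29 to 0.36 and an edgeR adjusted p of at most 0.0584. MYB93 lost it in 13 (WT replicates 2 to 6 and myb67 replicates 3 and 5 of experiment 1, WT replicates 4 and 5 and myb67 replicates 1 to 4 of experiment 2), with 0.28 to 0.35 and an edgeR adjusted p of at most 0.0658. MYB9 overlaps AT5G16780 in the annotation. MYB107 (AT3G02940) had 0.28 (SE 0.08; edgeR adjusted p = 0.136) and passed in limma-voom (adjusted p = 0.0262) and DESeq2 (adjusted p = 0.0399), while MYB41 (AT4G28110) had -0.06 (SE 0.17; edgeR adjusted p = 1) and MYB36 (AT5G57620) 0.17 (SE 0.07; edgeR adjusted p = 0.592).

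**Figure D3:**
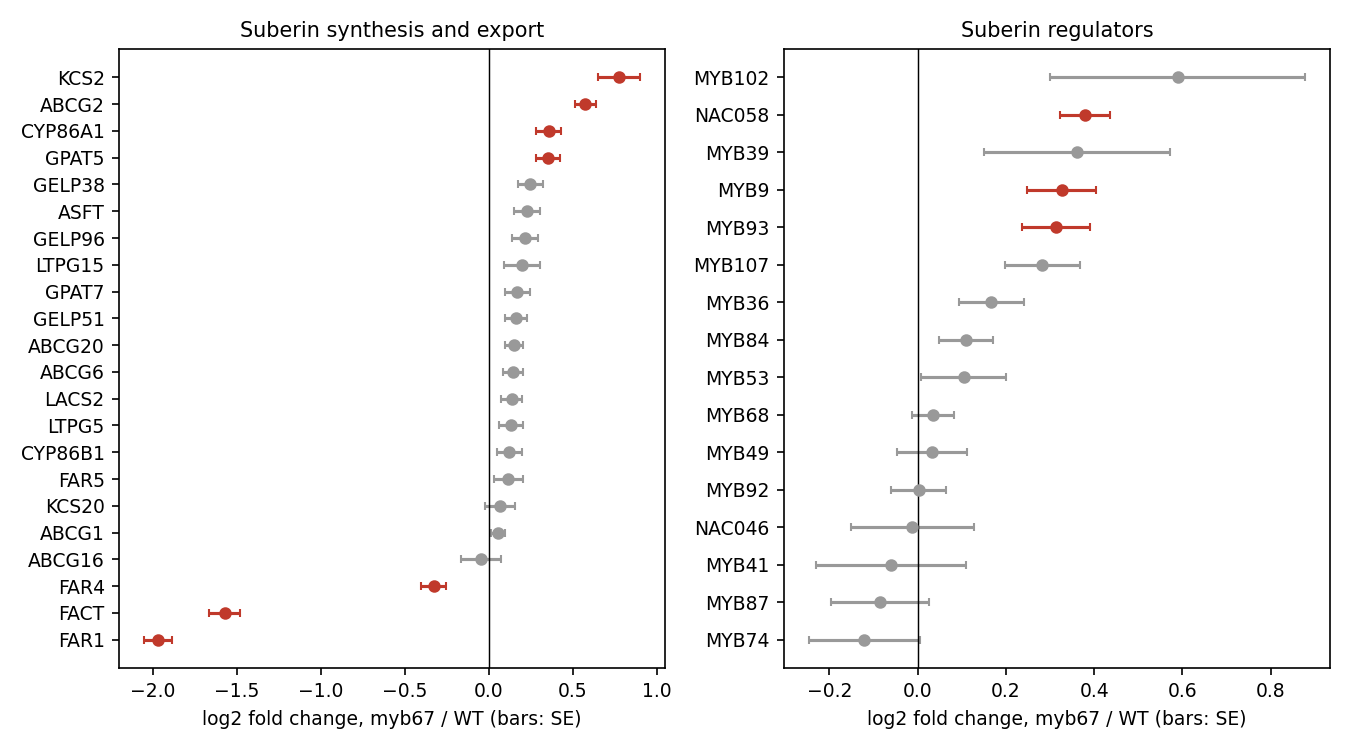
Log2 fold change over both experiments (x axis, bars are SE) of the 22 genes of suberin synthesis and export (left) and the 16 suberin regulators (right), with genes past an edgeR adjusted p of 0.05 in red. FAR1 (-1.97) and FACT (-1.57) lie far below 0, while KCS2 (0.78) is the highest of the 4 rises.

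Of 8 tested members of the heat shock list, 4 rose over both experiments, none fell and 4 did not pass (4 rose when adjusted over the list alone). The heat shock factor gene HSFA2 (AT2G26150) had a log2 fold change of 1.19 (SE 0.25), and the chaperone genes HSP90.1 (AT5G52640) 0.93 (SE 0.17), HSP70 (AT3G12580) 0.77 (SE 0.10) and HSP101 (AT1G74310) 0.50 (SE 0.09). In experiment 1, HSP90.1, HSP70 and HSP101 passed (edgeR adjusted p = 1.08e-05, 2.25e-04 and 4.39e-04) and HSFA2 did not (0.0908). In experiment 2 only HSP70 passed (edgeR adjusted p = 0.0260), while HSFA2 had 0.209, HSP101 0.4826 and HSP90.1 0.6015. HSP101 overlaps AT1G74300 in the annotation, and HSP70 lies among the 100 tested genes on either side of MYB67. The set passed by camera (adjusted p = 2.39e-09), with an estimated correlation (adjusted p = 0.0263), by fry (adjusted p = 0.00122) and by permutation of the list's mean (adjusted p = 0.00644). With the replicate pairs of experiment 2 in the model, camera with an estimated correlation gave an adjusted p of 0.0526. The mean log2 CPM of the list differed by 0.80 in experiment 1, where the libraries of both genotypes did not overlap, and by 0.18 in experiment 2. With an estimated correlation the list had a camera adjusted p of 0.00164 in experiment 1 and of 0.331 in experiment 2 (0.0413 there with the preset correlation). The test of the difference between experiments gave a camera adjusted p of 7.95e-06, and of 0.0794 with an estimated correlation, which with the replicate pairs of experiment 2 in the model was 0.0447. HSP90.1 differed between experiments with the pairs in the model (edgeR adjusted p = 0.00268) and not without them (edgeR adjusted p = 0.120).

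By camera, 2 further lists rose. Genes of developmental cell death passed (adjusted p = 6.23e-04; adjusted p = 0.589 with an estimated correlation), with 2 of 8 members higher, AT4G18425 (DMP4; 0.67, SE 0.09) and AT2G14095 (EXI1; 0.62, SE 0.14), and 6 not passing (2 when adjusted over the list alone). Its mean log2 CPM differed by 0.42 in experiment 2 (camera adjusted p = 9.73e-07, and 0.234 with an estimated correlation), while experiment 1 did not pass (camera adjusted p = 0.542). The difference between experiments gave a camera adjusted p of 0.00478, and of 0.557 with an estimated correlation. Genes of the hypoxia response passed (adjusted p = 0.0350; adjusted p = 0.589 with an estimated correlation), with 1 of 12 higher, the pyruvate decarboxylase gene PDC1 (AT4G33070; 0.31, SE 0.07), and 2 when adjusted over the list alone. The hypoxia list's mean log2 CPM differed by 0.31 in experiment 2 (camera adjusted p = 1.78e-07), where an estimated correlation gave 0.0631 and, with the replicate pairs in the model, 0.0358. Experiment 1 did not pass (camera adjusted p = 0.542). The list's call over both experiments was lost without WT replicate 1, 2, 4 or 5 or myb67 replicate 1, 3, 4 or 5 of experiment 2 (camera adjusted p of at most 0.149). The difference between experiments gave the list a camera adjusted p of 7.95e-06, of 0.0946 with an estimated correlation and of 0.0447 with that and the replicate pairs of experiment 2 in the model. AT2G14095 differed between experiments with the pairs in the model (edgeR adjusted p = 0.00268) and not without them (edgeR adjusted p = 0.318). The calls of AT2G14095 and AT4G33070 were lost without the 3 libraries of fewest counts (edgeR adjusted p = 0.0586 and 0.0629).

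Of the 3 lists that fell by camera, photosynthesis genes passed with an adjusted p of 7.61e-06, and with an estimated correlation the adjusted p was 0.589. None of its 21 tested members passed on its own, also when adjusted over the list alone, and all 21 had a negative log2 fold change. The fall came from experiment 1, where the list's mean log2 CPM differed by -1.10 (camera adjusted p = 1.87e-16), while in experiment 2 the list passed as higher (camera adjusted p = 0.0174). The difference between experiments gave a camera adjusted p of 2.08e-15. With an estimated correlation these were 0.561, 0.599 and 0.432. In experiment 1, WT replicates 3 and 6 had means of 6.38 and 6.63, and the other 10 libraries had 3.55 to 4.17. Without those 2 libraries the call was lost (camera adjusted p = 0.716). Jasmonate genes passed by camera (adjusted p = 1.44e-04; adjusted p = 0.589 with an estimated correlation), with none of 13 called and 5 lower when adjusted over the list alone. Its mean log2 CPM differed by -0.37 in experiment 2 (camera adjusted p = 3.01e-04, and 0.319 with an estimated correlation) and by -0.29 in experiment 1 (camera adjusted p = 0.109). There, myb67 replicate 3 had 4.597, above all 6 WT libraries, and the difference was -0.474 without it and -0.167 without myb67 replicate 4. Glucosinolate genes passed by camera (adjusted p = 5.31e-04; adjusted p = 0.589 with an estimated correlation), with none of 18 called under either adjustment. Its mean log2 CPM differed by -0.35 in experiment 2 (camera adjusted p = 5.98e-06, and 0.299 with an estimated correlation), while experiment 1 did not pass (camera adjusted p = 0.542). The difference between experiments gave a camera adjusted p of 0.0156 (0.557 with an estimated correlation).

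**Figure D4:**
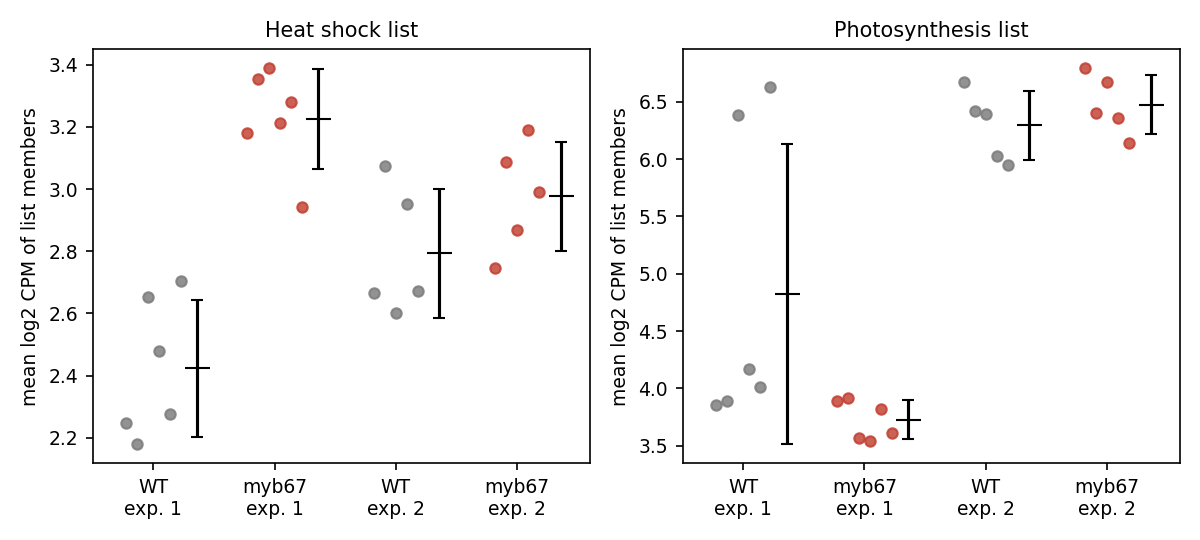
Mean log2 CPM of the heat shock list (left) and the photosynthesis list (right) in each library (dots), by genotype and experiment, with mean and SD (bars). In experiment 1 all 6 libraries labelled myb67 lie above the 6 WT libraries for heat shock, and WT replicates 3 and 6 stand apart for photosynthesis at 6.38 and 6.63.

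The other 20 lists did not pass by camera over both experiments. Their adjusted p was 0.0679 for flavonoid genes, 0.0844 for cutin and wax, 0.0946 for salicylate defence and for the xylem secondary wall, and 0.160 for root tip and cap. It was 0.234 for iron deficiency, triterpene clusters and touch or wounding, 0.364 for the clock, 0.409 for general phenylpropanoid genes and 0.437 for the abscisic acid response. Aquaporins, lateral root primordium and phloem had 0.668, Casparian strip and endodermis 0.737, mitosis 0.782, cambium and lignin polymerisation 0.831, and root hairs and phosphate starvation 0.966. Within these lists, GPAT6 (AT2G38110), an acyltransferase of cutin, rose by 0.76 (SE 0.11), the lignin gene CCR1 (AT1G15950, which overlaps AT1G15960) fell by 0.32 (SE 0.07) and the aquaporin gene PIP2;6 (AT2G39010) fell by 0.40 (SE 0.08). Adjusted over the list alone, cutin and wax had 1 rise and 3 falls, salicylate defence 1 and 2, touch or wounding 1 and 1, iron deficiency 1 rise, and xylem, phenylpropanoid and aquaporin lists 1 fall each. With the replicate pairs of experiment 2 in the model, cutin and wax (adjusted p = 0.0424) and flavonoid genes (adjusted p = 0.0134) passed as lower, each with an adjusted p of 0.444 with an estimated correlation. In experiment 2, camera gave phloem (adjusted p = 0.00409), xylem (0.0133) and cambium (0.0232) as higher. Touch or wounding (0.00274), cutin and wax and salicylate defence (both 0.0263), and endodermis and root hairs (both 0.0319) were lower there. Iron deficiency was higher in experiment 1 (camera adjusted p = 0.0265). An estimated correlation gave at least 0.319 for each of these.

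Each experiment was also tested for the genotype effect. In the fit of the 4 groups, 135 genes passed in experiment 1 (68 up, 67 down) and 288 in experiment 2 (135 up, 153 down). Without WT replicates 3 and 6 of experiment 1 the count of that experiment was 81, and DESeq2 gave 275. Each experiment fitted from its own libraries gave 180 and 136 genes. They shared 50, all with the same sign: 26 rises, where independent lists would share 0.262, and 24 falls, where they would share 0.257. In experiment 2, WT and myb67 libraries of the same replicate number deviated together from their group means, although those of replicate 5 matched replicate 4 of the other genotype best. With the number as a block, 980 genes passed in experiment 2 (edgeR; 301 up, 679 down), and 1627 (659 up, 968 down) when that experiment was fitted from its own 10 libraries. Of these 1627, 1620 were tested in experiment 1, where 757 had the same sign, about as many as unrelated effects would give. Of the 757, however, 254 had an unadjusted edgeR p under 0.05 in experiment 1. Among all 21683 genes tested, 1876 had such a p there, which is a lower share. With the same block, experiment 1 had 231 genes. Of 70 splits of the libraries within experiments, 5 gave as many genes in experiment 2 as the genotypes without the block, the genotypes included. Without WT replicate 1 of experiment 2, the unblocked count there was 509.

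The genotype effect differed between experiments for 15 genes (edgeR; 11 with a higher and 4 with a lower log2 fold change in experiment 2), and for 516 with the block. Without WT replicate 1 of experiment 2 the count was 23, limma-voom gave 6 and DESeq2 gave 41. AT5G44925 had a log2 fold change of 5.00 in experiment 1 and 1.37 in experiment 2 (edgeR adjusted p of the difference = 0.00117). The WT libraries of experiment 1 held only 0 to 4 counts of this gene, so its 5.00 rests on a level near 0. The cellulose synthase-like gene CSLB01 (AT2G32610) had -0.02 and 1.68 (edgeR adjusted p = 0.00117), and the myrosinase-binding protein gene MLP-300B (AT3G16440) 0.41 and 1.85 (edgeR adjusted p = 0.00417). AT5G44050 of the MATE efflux family had -0.92 and 0.06 (edgeR adjusted p = 0.00597), and AT4G14060 had -0.63 and 0.52 (edgeR adjusted p = 0.00657). Without the 3 libraries of fewest counts 6 genes passed, and 8 without WT replicates 3 and 6 of experiment 1. The WT libraries of experiments 1 and 2 also differed in lists of tissue markers. Their mean log2 CPM was 4.862 and 2.417 for Casparian strip and endodermis, 4.668 and 1.553 for root hairs and 3.99 and 5.172 for cambium. For suberin synthesis it was 6.398 and 6.458. Whether the differences of the genotype effect follow from this was not tested.

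The authors' deposited table, a comparison of myb67 with WT, lists 417 genes with an adjusted p under 0.05, 223 up and 194 down. A DESeq2 fit of the rounded counts with the experiment as a term gave the deposited log2 fold changes to within 1e-06 for all 32747 genes that have one, and the same 417 calls. Without that term DESeq2 called 139 genes, 138 of them shared with the authors' deposited table. The edgeR fit and the authors' deposited table shared 324 calls, all of the same sign, with 93 in the deposited table alone and 2 in the edgeR fit alone. For MRD1 the deposited table gives a log2 fold change of -7.76 but no adjusted p, so it is not among the deposited calls. Of the deposited calls, 11 were genes too low to be tested here. For MYB67 the authors' deposited table gives a log2 fold change of 0.79 and an adjusted p of 4.71e-09.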

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

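All tests in this part except that of the shoot markers were chosen after the result they test had been seen. The counts over both experiments, in experiment 1 and for the difference were set against 70 splits of the libraries within experiments, the genotypes included. For the 326 genes over both experiments, 1 of the 70 gave as many, and the highest other split gave 8, so chance could be excluded. For the 135 genes of experiment 1 (81 without WT replicates 3 and 6, a count not set against splits), 3 of 70 gave as many, with 671 in the highest other. The 70 splits are too few to place that share under 0.05, and chance was not excluded for this count. A split with several times the real count points to a structure of the samples. For the 288 genes of experiment 2 (509 without WT replicate 1), 5 of 70 gave as many, so the splits could not exclude chance for that count. For the 69 genes called in both experiments with the same sign, 1 of 70 gave as many, with 0 in the highest other, so chance could be excluded for these. For the 288 genes of experiment 2, the highest other split gave 1695 and parted 1 of the 5 pairs of equal replicate number. None of the other splits at or above that real count parted all 5 pairs, as the genotypes do. With the pairs as a block, the highest other of 16 splits that part all pairs gave 1 gene where the genotypes gave 1627, and 16 splits are too few for a share under 0.05. Of the gene lists, 34 of 100 splits gave at least the 8 lists of camera, up to 14, so chance could not be excluded. With an estimated correlation, 2 of 100 splits gave as many as the 1 list that passed, with 1 in the highest other. For this fit, without the replicate pairs of experiment 2, the share is under 0.05, but 100 splits place it only roughly. Over both experiments with the pairs in the model, 0 lists passed (heat shock had an adjusted p of 0.0526), while heat shock passed in experiment 1 (adjusted p = 0.00164) and hypoxia in experiment 2 (adjusted p = 0.0358).

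The genotype effect differed between experiments for 15 genes (23 without WT replicate 1 of experiment 2), and 3 of 70 splits gave as many. The highest other gave 539, which again points to a structure of the samples. The splits take away the genotype effect itself, so they do not test whether that effect was equal in both experiments, and chance was not excluded. With the block in experiment 2 only, 573 genes differed, and 1 of 16 splits, the genotypes, gave as many, with 137 in the highest other. These splits left the genotypes of experiment 1 in place, so they are no measure of equal effects in both experiments. There too the splits are too few for a share under 0.05. The log2 fold change was higher in experiment 2 by 1.44 for MLP-300B, by 1.70 for CSLB01, by 0.98 for AT5G44050 and by 1.14 for AT4G14060. For AT5G44925 the difference was -3.63, with 0 to 4 counts per WT library of experiment 1.

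Photosynthesis genes were lower in libraries labelled myb67 of experiment 1, where WT replicates 3 and 6 stood apart, and a candidate explanation is shoot tissue in those 2 libraries. The mean log2 CPM of 8 tested shoot markers outside photosynthesis (of 12 written down before the test, 2 of the 8 also in the cutin and wax list and 5 with a mean of at least 1 CPM in the other libraries of experiment 1) lay in both above the highest of the other 10, by 0.173 in the lower. RBCS1A had 217 and 443 CPM in them against 45.3 to 70.8 in the other 10, and LHCB1.3 had 355 and 442 against 96.3 to 161. Removal of lateral roots and a cut at the hypocotyl base would leave out most shoot tissue, and all 10 libraries of experiment 2 had high photosynthesis means (5.95 to 6.79) with lower shoot markers (1.59 to 2.23), so the source stays open. Without the 2 libraries the difference of the means was -0.256 (exact permutation p = 0.0524 over 210 splits, two-sided), which leaves a smaller genotype difference open.

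MYB67 was higher in libraries labelled myb67. Exchange of single libraries is argued against, since 0 libraries labelled myb67 lay at or below a WT library of their experiment. A rise of a neighbouring gene that carries into MYB67 is argued against as well. The neighbours AT3G12710 (-0.19) and AT3G12730 (0.18) lay below the rise of MYB67 by more than 2 SE. Transcription running on from a neighbour of unchanged level was not tested, since it need not raise that neighbour's count. An exchange of all labels would mirror the log2 fold change of 0.79 and every other direction, and no value outside the labels fixes the genotype, so labels as given and labels exchanged cannot be told apart for MYB67. An effect of the allele on its own transcript, a biological explanation, was not tested, as the allele's place and kind are not given.

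Called genes often stood side by side in the genome, in 21 pairs of neighbours called in the same direction. Reads shared by overlap are argued against for 11 pairs, since 10 of the 21 overlap in the annotation and 11 do not, while reads shared between related neighbours such as AZI1 and EARLI1 were not tested. Chance is argued against, since the highest of 10000 random gene sets held 9 pairs without overlap (permutation p = 1e-04, the smallest they can give). A sequence difference that travelled with MYB67 is argued against, since 20 of the 21 pairs lay outside the 100 tested genes on each side of it. For the overlapping neighbours MRD1 and HEI10, HEI10 lost 40.31 CPM in experiment 1, where MRD1 had 43.35 CPM in WT, and 42.4 against 52.15 CPM in experiment 2, so shared reads and a fall of both cannot be told apart by these counts, and differences of sequence elsewhere between the lines were not tested.

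Single libraries far from the others of their group, by the gap to the nearest library over the group's range, numbered 21 of 424 groups of values, where chance gives 21.2. WT replicate 1 of experiment 1 was high for NAC046 (0.652), CYP86B1 (0.637), MYB93 (0.712) and the share of AT3G41768 (0.641). In WT of experiment 1, replicate 5 was high for ABCG1 (0.712), and replicate 3 was high for CSLB01 (0.678) and low for HEI10 (0.723). Among libraries labelled myb67 of experiment 1, replicate 4 was low for AT1G74460 (0.636), CYP702A6 (0.686) and ABCG31 (0.733), and replicate 6 was low for MLP-300B (0.684) and high for MRD1 (1). There, replicate 5 was high for AT2G23540 (0.671), replicate 1 was high for AT4G32950 (0.654) and replicate 3 was low for the phosphate starvation list (0.632). In WT of experiment 2, replicate 5 was low for HSFA2 (0.834) and high for the general phenylpropanoid list (0.747), replicate 4 was low for HSFB3 (0.886) and replicate 2 was low for ABCG31 (0.842). Among libraries labelled myb67 of experiment 2, replicate 5 was low for AT5G37690 (0.778) and replicate 2 was high for BAS (0.733). These gaps cover named genes, list means and the share of AT3G41768, not the profile over all genes. On the first principal component of log2 CPM in experiment 1 (24.1% of the variance), WT replicate 1 lay at 75. The other libraries of that experiment lay at -22.9 to 13.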

How the results depend on the processing

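The block in experiment 2 only, unrounded values, the permutation of list means and the settings that leave out several libraries or overlapping genes were chosen after the data were seen. For the 43 called named genes, 1457 of 1499 values under alternatives kept direction and call, 42 lost the call and 0 reversed. Of 924 list values, 841 kept direction and side of the threshold, 34 lost the call, 45 gained one and 4 reversed. Over both experiments the count was 325 with RLE or upper quartile, 322 without a filter, 386 with the block and 479 with the block in experiment 2 only. It was 387 with limma-voom, 417 with DESeq2 and 271 without overlapping genes. The following values moved, and the cause was not tested unless stated. The block gave 231 genes in experiment 1, 980 in experiment 2 and 516 for the difference, and the block in experiment 2 only gave 280, 1050 and 573. Limma-voom gave 6 for the difference and 14 lists, and DESeq2 gave 275 in experiment 1 and 41 for the difference. No experiment term gave 83 genes over both experiments and 0.78 for MYB67, which lost its call, and 138 calls shared with the authors' deposited table in DESeq2. The 10 libraries of experiment 2 alone gave 136 genes, 1627 with the block, and 14 lists. A log2 fold change of at least 1 in size left 80, 58 and 93 genes over both experiments, in experiment 1 and in experiment 2, by its own construction. An estimated correlation left 1 list, fry 2 and permutation 1, while experiment 1 alone gave 6. Fewer libraries gave 81 genes in experiment 1 and 8 for the difference without WT replicates 3 and 6, and 6 for the difference without the 3 libraries of fewest counts. The list adjusted p values that changed side were as follows. With the block, cutin and wax had 0.0190 and flavonoid genes 0.0155, and with the block in experiment 2 only 0.0424 and 0.0134. With limma-voom weights, cutin and wax and triterpene clusters had 0.0443, iron deficiency and touch or wounding 0.0173, root tip and cap 0.0481 and xylem 0.0419. In experiment 1 alone, developmental cell death (0.531), glucosinolate and jasmonate (both 0.1) and suberin synthesis (0.343) lost their calls, flavonoid genes (0.0279), iron deficiency (0.000141) and root hairs (0.00411) gained one, and hypoxia reversed (0.276). In experiment 2 alone, cambium (0.0333), cutin and wax (0.0414), lateral root primordium (0.0347), phloem (0.00161), touch or wounding (0.00576) and xylem (0.0357) gained a call, and photosynthesis reversed (0.000604). With the block there, cambium (0.00116), Casparian strip (0.0157), phloem (0.000512) and touch or wounding (0.00131) gained one, heat shock lost its call (0.0810), and photosynthesis (5.31e-08) and root hairs (0.0260) reversed. An estimated correlation gave 0.146 for suberin regulators and 0.589 for the other 6 lists that lost their calls. Fry gave 0.367 for developmental cell death, glucosinolate and jasmonate, 0.477 for hypoxia and photosynthesis and 0.797 for suberin synthesis. Permutation gave 0.195 for developmental cell death, jasmonate and suberin regulators, 0.534 for glucosinolate, 0.607 for hypoxia and photosynthesis and 0.948 for suberin synthesis. Without the 3 libraries of fewest counts, flavonoid genes had 0.0192, root tip and cap 0.0473 and touch or wounding 0.0176. Without WT replicates 3 and 6 of experiment 1, flavonoid genes had 0.0279, salicylate defence 0.0249 and photosynthesis 0.716. Leaving out each library gave 289 to 327 genes over both experiments, 104 to 170 in experiment 1, 7 to 11 lists and 0.73 to 0.85 for MYB67. For lists it gave adjusted p values of 0.0315 to 0.249 for cutin and wax, 0.00536 to 0.287 for flavonoid genes, 0.00594 to 0.149 for hypoxia, 0.0106 to 0.542 for iron deficiency, 0.0357 to 0.519 for root tip and cap, 0.0367 to 0.274 for salicylate defence, 0.00614 to 0.488 for touch or wounding, 0.00189 to 0.684 for triterpene clusters and 0.00796 to 0.384 for xylem. In experiment 2 it gave 192 to 509 and for the difference 10 to 23, the highest of both without WT replicate 1 of experiment 2. No fit at equal depth was made, so what the lower depth of experiment 1 limits was not tested. From its own libraries experiment 1 gave 180 calls and experiment 2 gave 136. In the fit of the 4 groups, 66% and 70% of 1.5-fold changes were called in libraries simulated without replicate pairs.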

Other observations

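The 12 gene families below were picked after the called genes had been seen, and neighbours within a family are not independent, so the Fisher's exact tests run on them decide nothing and only the counts are given. Of 69 tested lipid-transfer protein genes, 6 fell: AT3G58550, AT2G18370 (log2 fold change -1.67) and 4 in 1 run of neighbours, AZI1 (AT4G12470, -1.36), EARLI1 (AT4G12480, -1.34), AT4G12490 (-1.16) and AT4G12500 (-1.09). Of 31 small heat shock protein genes outside the fixed list, 3 rose, AT5G51440 (1.01) among them. NAC genes had 5 rises and 1 fall of 74, with NAC038 (AT2G24430, 0.55) and NAC099 (AT5G56620, 0.55, overlapping AT5G56610) among the rises. Cytochrome P450 genes had 8 rises and 6 falls of 184, ABC transporters 4 and 3 of 58, peroxidases 2 and 4 of 82, alpha/beta hydrolases 2 and 4 of 159, MYB domain proteins 3 and 1 of 118 and myrosinase-binding or MLP-like proteins 1 and 2 of 10. The pollen Ole e 1 family had 3 rises of 18, UDP-glycosyltransferases 3 falls of 115 and GDSL lipases 2 falls of 60.

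The receptor kinase gene GSO1 (AT4G20140), left out of the endodermis list because its listed name was SGN3, had a log2 fold change of 0.65, and its span overlaps AT4G20150. The rule compared names only, so a member left out can be the intended gene under another name. The endodermis list was tested without it. Of the genes called in experiment 2 with the block, 1620 were tested in experiment 1, where 757 had the same sign and 254 of these an unadjusted p under 0.05. Effects unrelated between experiments would give about as many equal signs, but fewer genes with such a p. In experiment 1, 1876 of all 21683 tested genes had one. Without the block, 116 genes called from the libraries of experiment 2 alone were tested in both experiments, and 114 had the same sign in experiment 1.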
